A study of Homo sapiens with 6 samples.

How the data were processed

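RNA was extracted with Trizol from PANC-1-IN cells, a pancreatic cancer line named so in the labels, and libraries were made with a NEBNext Ultra RNA kit and sequenced as 150-base read pairs on a NovaSeq instrument, per the labels' protocols. The series holds 3 control libraries and 3 libraries of cells with GATM knocked down, and the group and number of each library were taken from its title. The titles begin with Lvcon and LvshGATM, which read as a lentiviral control and a lentiviral short hairpin against GATM. The sources used here do not state whether the numbers 1 to 3 stand for separate cultures, repeats of one culture or different knock-down constructs.

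The authors deposited a table of raw read counts per gene symbol and a table of FPKM (fragments per kilobase of gene length, scaled to the counted reads of the library), each with one column per library. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 were used and the genome builds are hg19 and GRCh37, with no role or order given. The annotation version, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Overlapping genes and near-identical gene copies are therefore uncertain. The deposited FPKM values equalled the counts divided by gene length and by the column total, with gene lengths that differed between libraries by a relative spread of at most 1.44e-06. The FPKM table thus carries the same measurements as the count table, and it served as another unit for the tests and as the source of gene lengths.

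The count table has 26466 rows, of which 19846 were above 0 in at least 1 library. It contains 28 names that read as dates, as a spreadsheet writes some gene symbols; 2 rows repeat an earlier name, and each such row was kept apart. These rows stayed in the tests but are not named. The table has no symbols of mitochondrially encoded genes, so that list could not be tested. Totals ran from 16512220 to 17535763 counts per library. In each pair of libraries of one group the counts differed by more than counting noise, with a mean chi-square per gene of 3.03 to 27.16 on 1 degree of freedom, so no library was treated as a duplicate.

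Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 14009 genes, and libraries were scaled with TMM factors. Knock-down and control were compared with the quasi-likelihood F test (estimateDisp and glmQLFit, both robust, in the newer form with legacy set to FALSE), with no covariate. In a first look at the data the quasi-likelihood fit was run in its older form, the default of this version, and that form is one of the alternatives. All adjusted p-values are Benjamini-Hochberg values, and a gene was called changed under 0.05. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values (counts per 1000000 counts of a library) are TMM-normalised and given as mean ± SD over 3 libraries.

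The test, the gene lists and the rule for naming genes were fixed before the data were examined. The 34 lists were written from general knowledge and hold 1155 different genes of the table. The 30 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Camera with a correlation estimated from the residuals and fry, the rotation test of limma 3.58.1, were run beside it; fry tests whether a list's genes move one way on balance and does not compare them with other genes. The percentile of each list's median among 10000 random lists of the same size, drawn from 50 bins of mean expression, was added after the data were examined. Random lists do not carry the correlation between genes of a list, so shares of such lists are not p-values. The rule named GATM; the 6 largest rises and the 6 largest falls among changed genes with at least 5 CPM in the higher group, no overlap between the groups, and a symbol that is not clone-based, LOC or pseudogene-like; the 4 smallest p-values not already named; and, per list, up to 2 changed members with the largest fold change and at least 1 CPM, or up to 4 where the list passed. It gave 106 genes. The 16 of them that lost their call when 1 library was left out are not given a direction in the text.

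Transcript GC content came from the longest GENCODE v29 transcript of each gene, matched by current or older symbol, for 13275 of the 14009 genes tested (94.8%). That annotation is on another genome build than the files, so it gave GC content alone, and a RefSeq table of GRCh38.p14 gave gene order alone; no coordinates are printed. The oxidative phosphorylation list had a GC value for 59 of its 72 tested members; the other lists tested lacked at most 2.

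Alternatives fixed in advance were other scalings (RLE factors, upper-quartile factors, library totals), the DESeq2 1.42.0 Wald test, the older quasi-likelihood form, no low-count filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a filter of 1 FPKM in 3 libraries or without it, leaving out each library in turn, a threshold of 0.01, a test against 1.5-fold (glmTreat), camera with an estimated correlation, and fry. Fits with offsets for GC content, alone or with gene length (lowess, span 0.3), were added after the libraries were seen to differ by GC content. A first test for genomic DNA classed genes by their mean over both groups, which limits the excess a class can show; it was replaced by one with classes from 1 control library. On counts simulated for this comparison, over 13868 genes, the main test recovered 68.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 6.1% of its calls were false. With a GC trend per library added to the simulated counts (13847 genes), the main test recovered 41.8% of the 1.5-fold genes and the fit with GC offsets recovered 67.2%. The simulation changed few genes: the main test made 198 calls in it, against 4276 in the data, and recovery depends on that share. Its gene dispersions came from the real libraries and already held their GC spread, so the added trend counted that spread again. These rates therefore do not describe power in the real comparison.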

Results

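Gene expression was measured by bulk RNA sequencing in PANC-1-IN cells, a pancreatic cancer line, in 3 libraries of control cells and 3 libraries of cells with GATM knocked down. GATM encodes glycine amidinotransferase, the enzyme that makes guanidinoacetate, the precursor of creatine, from arginine and glycine. The comparison asks which transcripts differ when GATM expression is lowered. The title of the study concerns guanidinoacetate synthesis, metastasis and histone marks of active transcription. Control libraries held 17155217, 17535763 and 16512220 counts, and knock-down libraries held 16652251, 16758991 and 17238155. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

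GATM itself was lower in each of the knock-down libraries than in each of the control libraries. It had 282, 340 and 370 counts in the controls and 145, 160 and 129 in the knock-down libraries. This corresponds to 19.9 ± 2.61 CPM in control cells and 8.35 ± 0.98 CPM in knock-down cells (SD, n = 3), a log2 fold change of -1.25 (SE 0.14, edgeR quasi-likelihood adjusted p = 1.48e-04). The knock-down thus left 0.419 of the control level of the transcript.

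Knock-down cells had more transcripts of the phosphate carrier SLC34A2, the amino acid transporter SLC7A8, the splicing factor ESRP1, the methionine adenosyltransferase MAT1A and the protease inhibitor SPINT1. They had fewer of the protocadherin PCDH20, the transcription factor NR2F1, the metalloproteinase MMP16, the non-coding RNA H19, the receptor CALCRL and the signalling protein SHH. SLC34A2 rose from 0.22 ± 0.13 to 6.41 ± 0.93 CPM (log2 fold change 4.81, SE 0.34, adjusted p = 5.46e-06) and SLC7A8 from 0.46 ± 0.16 to 12.5 ± 1.10 CPM (4.74, SE 0.24, adjusted p = 7.30e-07). MAT1A rose from 0.52 ± 0.14 to 6.80 ± 0.51 CPM (log2 fold change 3.69, SE 0.25). PCDH20 fell from 13.3 ± 0.57 to 1.06 ± 0.27 CPM (log2 fold change -3.65, SE 0.19, adjusted p = 7.30e-07), SHH from 30.8 ± 1.27 to 5.14 ± 0.52 CPM (-2.58, SE 0.12) and H19 from 94.3 ± 23.1 to 14.0 ± 1.87 CPM (-2.75, SE 0.19). NR2F1, MMP16 and CALCRL had log2 fold changes of -2.85, -2.81 and -2.73. ALPPL2, an alkaline phosphatase, went from 7.06 ± 1.37 to 103 ± 10.8 CPM (log2 fold change 3.87), but it is a close copy of ALPP and the way reads shared by both were counted is not stated. The smallest p-values outside these genes belonged to TMEM255A (log2 fold change 3.17), the tight junction gene CLDN1 (-1.92), BEX2 (2.67) and BASP1 (1.58).

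**Figure D1:**
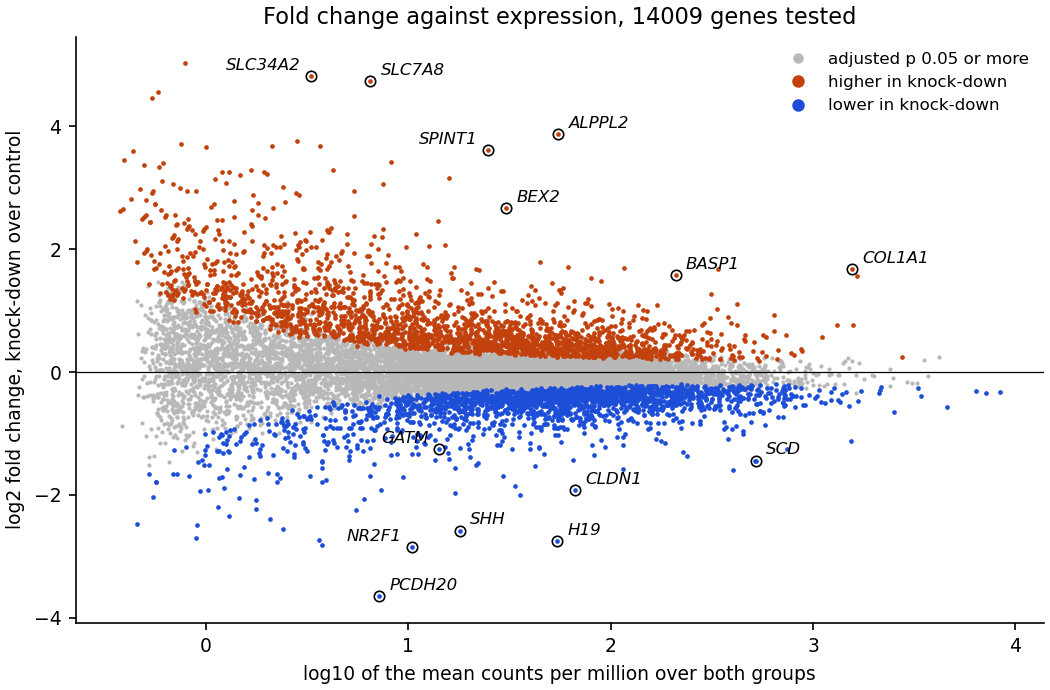
Log2 fold change of each of the 14009 tested genes (vertical axis, knock-down over control) against the log10 of its mean CPM over both groups (horizontal axis); coloured points passed an adjusted p of 0.05 and circles mark named genes. SLC34A2 lies at 4.81 and PCDH20 at -3.65, and rises outnumber falls among weakly expressed genes.

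Of 14009 genes tested, 4276 changed: 2216 were higher and 2060 lower in knock-down cells (51.8% higher; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 844 of them differed more than 2-fold. The first principal component held 63.5% of the variance and separated the groups. Among the 2289 tested genes with a mean under 3 CPM, 440 rose and 106 fell, with a median log2 fold change of 0.29, against 1776 and 1954 of the other 11720 genes, with a median of -0.02. Scaling by library totals gave 2811 higher and 1473 lower genes (65.6% higher). Tests on log2(FPKM + 1) gave 2175 and 1275 (63.0% higher), with 223 genes over 2-fold. The number of changed genes was 2574 without control 2, 2560 without knock-down 1 and 2699 without knock-down 2, and 6440 with offsets for the GC content of transcripts, of which 3464 were higher. The falls counted 1198, 1130 and 1217 without the same 3 libraries, and the rises 1376 without control 2 and 1430 without knock-down 1.

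Of 30 gene lists tested, 16 moved as a set at a preset correlation between genes; with a correlation estimated from the data, camera called 0 lists (6 at an unadjusted p under 0.05), while the rotation test fry, which does not compare a list with other genes, called 17. Of the 16, fry did not call the G2 and M phase, oxidative phosphorylation and ribosomal lists (adjusted p = 0.1394, 0.0962 and 0.0962). It called 4 others: arginine and polyamine metabolism (0.0287), the methionine cycle (0.0149), endoplasmic reticulum chaperones (0.0471) and YAP and TAZ targets (0.0081). The estimated correlation was -0.0037 for interferon, -0.0330 for histone and -0.0258 for p53 genes, below the preset 0.01. Correlation between members thus does not account for the lost calls of these lists. With an estimated correlation, camera also relies on the few residual degrees of freedom of 6 libraries. In other called lists the estimate was higher, up to 0.4799 for ribosomal genes.

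Epithelial genes rose together. Of 26 tested markers, 18 rose and 1 fell over all genes tested, and 19 rose and 1 fell adjusted over the list alone; the median log2 fold change was 0.75 (camera adjusted p = 1.78e-12; adjusted p = 0.0505 with an estimated correlation). ESRP1, a regulator of epithelial splicing, rose from 0.38 ± 0.13 to 5.29 ± 0.56 CPM (log2 fold change 3.77), and SPINT1, an inhibitor of membrane serine proteases, from 3.75 ± 0.84 to 45.8 ± 3.22 CPM (3.61). CDH1, which encodes E-cadherin, rose from 2.65 ± 0.28 to 12.2 ± 0.44 CPM. ST14, a protease that SPINT1 inhibits, rose with a log2 fold change of 2.09. The member that fell was CLDN1, from 105 ± 1.68 to 27.9 ± 0.41 CPM. Mesenchymal markers moved both ways: 7 of 32 rose and 7 fell on either adjustment, with a median of -0.02, a mean of 0.05 and an upward set test (camera adjusted p = 0.6936). The collagen genes COL1A1 and COL5A1 were among the rises, with log2 fold changes of 1.67 and 1.49, and COL1A1 went from 745 ± 68.2 to 2377 ± 139 CPM. Of the 26 epithelial genes, 8 had a mean under 3 CPM, and none of 10000 random lists matched on expression had a median as high as theirs (95% range -0.16 to 0.20).

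**Figure D2:**
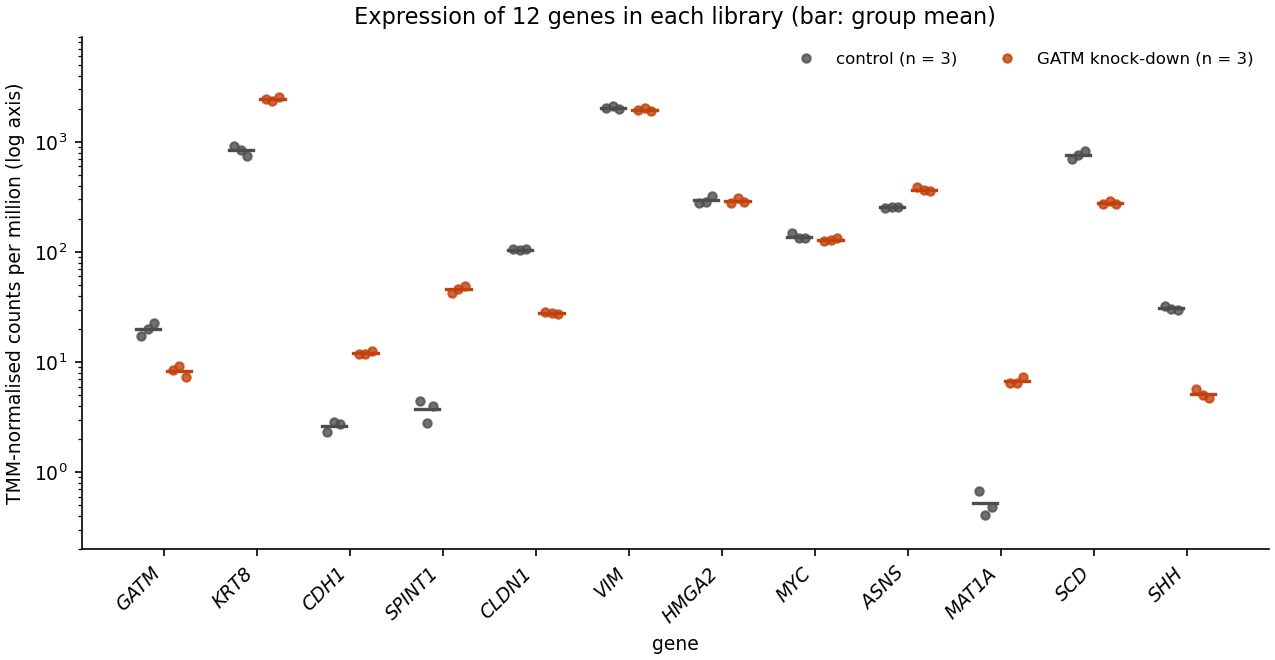
TMM-normalised CPM (log axis) of 12 genes in each library, with control libraries in grey, knock-down libraries in orange and bars at the group means (n = 3); KRT8, VIM, HMGA2, MYC and ASNS were chosen after their values were seen. SPINT1, CDH1, KRT8, ASNS and MAT1A lie higher in the 3 knock-down libraries than in the 3 controls, GATM, CLDN1, SCD and SHH lie lower, and the groups overlap for HMGA2, VIM and MYC.

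Genes of the amino acid and integrated stress response also rose: 27 of 37 tested members were higher and 1 lower (29 and 1 adjusted over the list alone), with a median log2 fold change of 0.43 (camera adjusted p = 1.78e-12; adjusted p = 0.0719 with an estimated correlation). The transcription factors CEBPB and ATF3 rose from 5.79 ± 1.53 to 18.9 ± 2.57 CPM and from 7.89 ± 0.83 to 25.8 ± 1.66 CPM, both a log2 fold change of 1.71. SESN2, a stress-inducible regulator of mTORC1, rose by 1.11 and NUPR1, at 0.70 ± 0.47 CPM in controls, by 1.58. Targets of p53 rose in 8 of 28 cases and fell in 3 (10 and 4 adjusted over the list alone; median 0.12; camera adjusted p = 0.0205; adjusted p = 0.2102 with an estimated correlation). PHLDA3 rose by 1.93, GADD45A by 1.33 and TNFRSF10B by 1.07 on the log2 scale, and SESN2 belongs to this list too. Among NRF2 and oxidative stress targets, 10 of 23 rose and 5 fell (12 and 5 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0323; adjusted p = 0.3954 with an estimated correlation). HMOX1, which encodes heme oxygenase, rose from 55.1 ± 8.32 to 179 ± 3.80 CPM (log2 fold change 1.70), OSGIN1 by 1.16, the cystine transporter gene SLC7A11 by 0.82 and ME1 by 0.68. The NRF2 list missed the threshold without knock-down 3 (camera adjusted p = 0.0665) and on FPKM, and the p53 list on FPKM. Over 19 alternatives their adjusted p ran from 0.0038 to 0.2568 and from 0.0101 to 0.1469. The p53 median was 0.05 without control 1, 0.19 without control 3 and 0.20 under library totals. Of 10000 random lists matched on expression, 0 had a median as high as the stress response list, 1 as high as the NRF2 list and 342 as high as the p53 list.

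Type I interferon response genes rose in 18 of 31 cases and fell in 1 (20 and 1 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 3.30e-07; adjusted p = 0.0503 with an estimated correlation). MX1, an antiviral GTPase, rose from 1.37 ± 0.27 to 6.95 ± 1.07 CPM (log2 fold change 2.34), IFI6 by 1.76, HERC6 by 1.70 and HERC5 by 1.42. Of NF-kB targets, cytokines and chemokines, 8 of 27 fell and 3 rose (8 and 4 adjusted over the list alone; median -0.11; camera adjusted p = 0.0260; adjusted p = 0.2900 with an estimated correlation). The chemokine genes CXCL1 and CCL2 had log2 fold changes of -2.07 and -2.00, the latter from 57.0 ± 7.17 to 14.3 ± 0.98 CPM, and LIF had -1.06, while IL32 rose by 1.17. The NF-kB list missed the threshold on filtered FPKM (camera adjusted p 0.0023 to 0.1494 over 19 alternatives), while its set test stayed downward. Its median was 0.02 without control 3, -0.16 without knock-down 1, -0.19 without knock-down 2, -0.03 under library totals and 0.0049 with offsets for GC content and length. Of 10000 random lists matched on expression, 607 had a median as low as the NF-kB list. Of the 31 interferon genes, 5 had a mean under 3 CPM, and none of 10000 random lists matched on expression reached their median (95% range -0.11 to 0.23).

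Replication-dependent histone transcripts rose in 10 of 14 cases and fell in none (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.09 (camera adjusted p = 1.02e-08; adjusted p = 0.0503 with an estimated correlation). HIST1H3B rose from 0.30 ± 0.16 to 3.02 ± 0.55 CPM (log2 fold change 3.29), HIST1H2BG by 2.49, HIST1H1C, a linker histone gene, by 2.06 and HIST1H4H by 1.98; reads shared between members of this gene family make single members uncertain. Of these 14 genes, 8 had a mean under 3 CPM; none of 10000 matched random lists reached the median (95% range -0.16 to 0.56). Genes of S phase fell in 18 of 45 cases and rose in 1 on either adjustment, with a median of -0.17 (camera adjusted p = 3.03e-04; adjusted p = 0.3357 with an estimated correlation). CDC45 and GINS2, which belong to the replicative helicase, had log2 fold changes of -0.85 and -0.75, and CDCA7 had -0.74. In the G2 and M phase list, 9 of 52 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0470; adjusted p = 0.5258 with an estimated correlation). LBR, PLK1 and CDCA8 had log2 fold changes of -1.02, -0.54 and -0.48. The median log2 difference of control 1 over control 3 was -0.19 for the S phase list and -0.25 for the G2 and M list. The G2 and M list missed the threshold without control 3 (camera adjusted p = 0.3670) and without knock-down 3 (0.1062). It missed it too under upper-quartile scaling, library totals, the stricter filter, the replicate block and filtered FPKM (0.0027 to 0.3670 over 19 alternatives). Its median was -0.05 without control 3 and -0.04 under library totals. The S phase median was -0.26 without control 1 and -0.10 under library totals. Of 10000 random lists matched on expression, 1914 had a median as low as the G2 and M list (95% range -0.16 to 0.02) and 85 as low as the S phase list (-0.15 to 0.06).

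Cholesterol and sterol synthesis genes fell in 13 of 31 cases and rose in none (14 and 0 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 6.21e-05; adjusted p = 0.0913 with an estimated correlation). The largest falls were in fatty acid desaturases that the list also holds: SCD went from 760 ± 65.9 to 280 ± 8.62 CPM and FADS2 from 95.4 ± 6.64 to 35.2 ± 3.27 CPM, both a log2 fold change of -1.44. DHCR7, of the last step of cholesterol synthesis, had -0.63. Of glycolysis and hypoxia targets, 12 of 36 fell and 6 rose on either adjustment (median -0.18; camera adjusted p = 0.0181; adjusted p = 0.4807 with an estimated correlation). ANGPTL4 fell from 172 ± 22.6 to 57.8 ± 3.81 CPM (log2 fold change -1.57) and PFKL, a phosphofructokinase gene, by 0.81, while CA12 and MXI1 rose by 1.22 and 0.94. Under library totals the medians were -0.15 for the cholesterol list and -0.10 for the glycolysis list. Of 10000 random lists matched on expression, 29 and 374 had medians as low.

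Cytosolic ribosomal protein genes fell in 25 of 77 cases and rose in none (29 fell and 1 rose adjusted over the list alone), with a median of -0.21 (camera adjusted p = 4.44e-05; adjusted p = 0.5258 with an estimated correlation). RPS15 went from 496 ± 67.7 to 344 ± 20.8 CPM (log2 fold change -0.53), and RPS26 had -0.74. Single genes of this family are uncertain because they share reads with pseudogenes. Nuclear genes of oxidative phosphorylation fell in 18 of 72 cases and rose in none (11 and 0 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0012; adjusted p = 0.5258 with an estimated correlation). NDUFS7, of complex I, went from 66.3 ± 12.8 to 42.9 ± 2.43 CPM. MYC and nucleolar targets fell in 15 of 57 cases and rose in 1 on either adjustment (median -0.15; camera adjusted p = 0.0035; adjusted p = 0.3954 with an estimated correlation). HSPD1, a mitochondrial chaperonin gene, had a log2 fold change of -0.74, TMEM97 -0.69 and NOC4L -0.57. These lists also differed between libraries of one group: the median log2 difference of control 1 over control 3 was 0.31 for the ribosomal list, 0.29 for oxidative phosphorylation and 0.15 for the MYC list. The medians between groups were smaller in size for the ribosomal and oxidative phosphorylation lists and of the same size for the MYC list. Under library totals the medians were -0.13, -0.13 and -0.07, and with offsets for GC content and length the MYC median was -0.09. Random lists matched on expression had a median of -0.12 (95% range -0.19 to -0.04) for the ribosomal list, -0.05 (-0.12 to 0.04) for oxidative phosphorylation and -0.08 (-0.17 to 0.01) for the MYC list. Of 10000 such lists, 50, 0 and 609 had medians as low. Genes of the real lists had estimated correlations of 0.48, 0.30 and 0.08, which random lists lack, so these shares are too small.

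**Figure D3:**
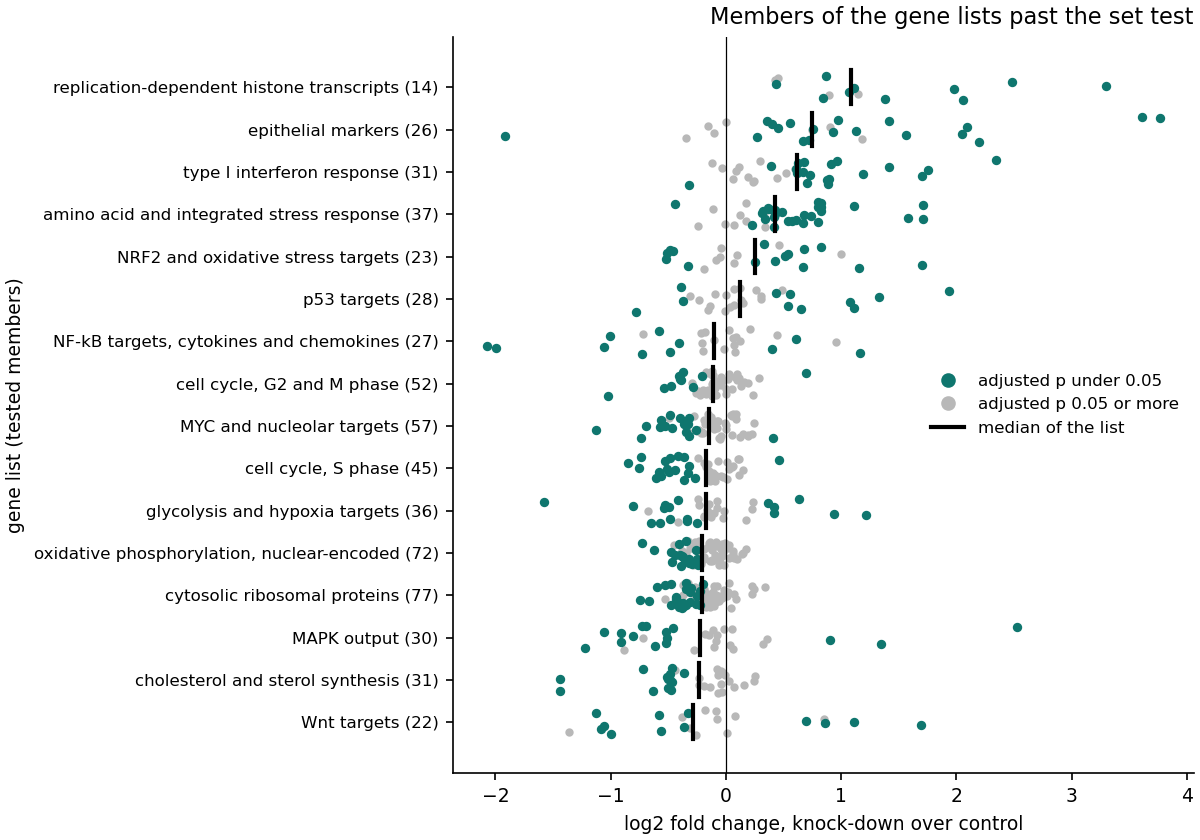
Log2 fold change (horizontal axis, knock-down over control) of each tested member of the 16 gene lists past the set test (vertical axis, tested members in brackets). Green points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars are list medians, from 1.09 for histone transcripts to -0.29 for Wnt targets.

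Among transcripts that report signalling, MAPK output genes fell in 12 of 30 cases and rose in 3 (13 and 4 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0081; adjusted p = 0.3357 with an estimated correlation). EGR1, an immediate early gene, and LIF had log2 fold changes of -1.22 and -1.06, while TGFA rose by 2.53 and DUSP5 by 1.34. The MAPK median was -0.14 without knock-down 1, -0.15 with offsets for GC content and length and -0.08 on log2(FPKM + 1). Wnt targets fell in 8 of 22 cases and rose in 4 on either adjustment, with a median of -0.29 (camera adjusted p = 0.0181; adjusted p = 0.3010 with an estimated correlation). DKK1 fell from 243 ± 6.22 to 112 ± 7.35 CPM (log2 fold change -1.13) and CD44 from 518 ± 9.64 to 244 ± 3.04 CPM (-1.09), while RNF43 and WNT10A rose by 1.70 and 1.11. The Wnt list missed the threshold without knock-down 1 (camera adjusted p = 0.0504) and without a low-count filter on counts or FPKM (0.0115 to 0.2174 over 19 alternatives). Its median was -0.19 without knock-down 2, -0.09 without a low-count filter on counts and -0.0043 on FPKM without a filter. Of 10000 random lists matched on expression, 18 had a median as low as the MAPK list and 10 as low as the Wnt list. TGF-beta and BMP targets (8 of 28 fell and 4 rose, 9 and 4 adjusted over the list alone; camera adjusted p = 0.1224) and YAP and TAZ targets (9 of 28 fell and 6 rose, 9 and 7 adjusted over the list alone; camera adjusted p = 0.1466) did not pass in camera; the YAP and TAZ list passed in fry (adjusted p = 0.0081). INHBA and WWTR1, which encodes TAZ, fell with log2 fold changes of -2.34 and -1.30, and ID2 rose by 1.07.

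Neither the lists of metabolic genes closest to GATM nor those of histone-modifying enzymes passed in camera, which compares a list with the other genes. These are transcript levels, which measure neither guanidinoacetate nor histone marks, so they do not test what the study's title concerns. Of 7 tested genes of creatine and guanidinoacetate metabolism, 2 rose and 2 fell, GATM among them (3 and 2 adjusted over the list alone; camera adjusted p = 0.5170). The rises were CKMT1A and CKMT1B (log2 fold changes 3.71 and 2.64), near-identical copies whose reads cannot be told apart with certainty. GAMT, which methylates guanidinoacetate to creatine, had 31.5 ± 2.97 CPM in control and 23.4 ± 3.75 CPM in knock-down cells (log2 fold change -0.43, edgeR adjusted p = 0.0299). Its call was lost without control 1 (0.0510), control 2 (0.0879), knock-down 1 (0.1180) or knock-down 2 (0.1285), and under library totals, the replicate block and FPKM. Of 28 arginine and polyamine genes, 6 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.00; camera adjusted p = 0.4275; fry adjusted p = 0.0287), and ASS1 and CPS1, of the urea cycle, rose by 1.03 and 0.83. Of 27 methionine cycle and one-carbon genes, 7 rose and 5 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.3101; fry adjusted p = 0.0149), with a median of -0.03 but a mean of 0.17 and an upward set test; ALDH1L2 rose by 0.93 and MAT1A as given above. Histone-modifying enzymes linked to activating marks, among them the H3K27 demethylases KDM6A and KDM6B, fell in 7 of 32 cases and rose in 5 (8 and 5 adjusted over the list alone; camera adjusted p = 0.4412), with SETD7 higher by 0.54. Enzymes that remove activating or add repressive marks fell in 6 of 36 cases and rose in 3 on either adjustment (median 0.01, mean -0.04, a downward set test, camera adjusted p = 0.4801), and HDAC3 had a log2 fold change of -0.76.

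Lists of cell movement moved both ways as well. Of 46 filopodia and actin assembly genes, 7 rose and 5 fell (3 and 2 adjusted over the list alone), with a median of -0.03, a mean of 0.02 and a downward set test (camera adjusted p = 0.8833); the median was positive under upper-quartile scaling, library totals, FPKM and GC content offsets, and without control 3. LPAR1, a receptor for lysophosphatidic acid, had a log2 fold change of -2.40. Of 33 integrin and focal adhesion genes, 7 rose and 8 fell on either adjustment, with a median of -0.04, a mean of 0.02 and a downward set test (camera adjusted p = 0.5919); ITGA10 had a log2 fold change of -1.19. Of 28 extracellular proteases and inhibitors, 4 rose and 7 fell on either adjustment (camera adjusted p = 0.1626), with MMP16 falling from 6.54 ± 0.96 to 0.92 ± 0.12 CPM. Chaperones of the endoplasmic reticulum and the unfolded protein response fell in 11 of 33 cases and rose in 5 on either adjustment (camera adjusted p = 0.1224; fry adjusted p = 0.0471). This list passed in camera without control 1 (0.0324), with offsets for GC content and without the low-count filter (0.0324 to 0.3366 over 19 alternatives). PDIA4 fell from 598 ± 15.1 to 299 ± 6.48 CPM, while HSPA5, the main chaperone of this compartment, rose from 980 ± 14.2 to 1660 ± 35.8 CPM. Of the classical subtype genes of pancreatic cancer, 2 of 8 rose and 2 fell on either adjustment (camera adjusted p = 0.5831), with FOXA3 and GATA6 higher by 1.43 and 1.11. Of 11 basal-like subtype genes, 2 rose and none fell on either adjustment (median 0.00, mean 0.17, an upward set test, camera adjusted p = 0.7465).

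Markers of other cells were mostly below the count filter. Of 21 blood and immune markers, 4 were tested; 2 rose and none fell on either adjustment, namely CD8A (2.44 ± 0.74 to 6.30 ± 0.99 CPM) and CD68 (98.4 ± 16.7 to 142 ± 5.04 CPM). Of 13 endothelial markers, 4 were tested, of which 2 rose and 1 fell on either adjustment, and of the 24 acinar and endocrine markers, 4 were tested and 0 changed in the edgeR test (0 at an unadjusted p under 0.05). These lists were too small for a set test, and no mitochondrially encoded gene is in the table.

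Libraries also differed within a group by the GC content of transcripts. Across 13275 genes, which are not independent replicates, the difference of control 1 over control 3 had a Spearman correlation of 0.70 with GC content, that of knock-down 3 over knock-down 2 had 0.54, and the log2 fold change between groups had -0.12. Offsets for GC content and length lowered the biological coefficient of variation from 10.01% to 5.75%. With these offsets the ribosomal list had a median of -0.15, the oxidative phosphorylation list -0.14, the histone list 1.16, the epithelial list 0.85 and the interferon list 0.61. On FPKM without a filter, which adds genes with few counts, the histone, epithelial and interferon medians were 0.44, 0.42 and 0.30.

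**Figure D4:**
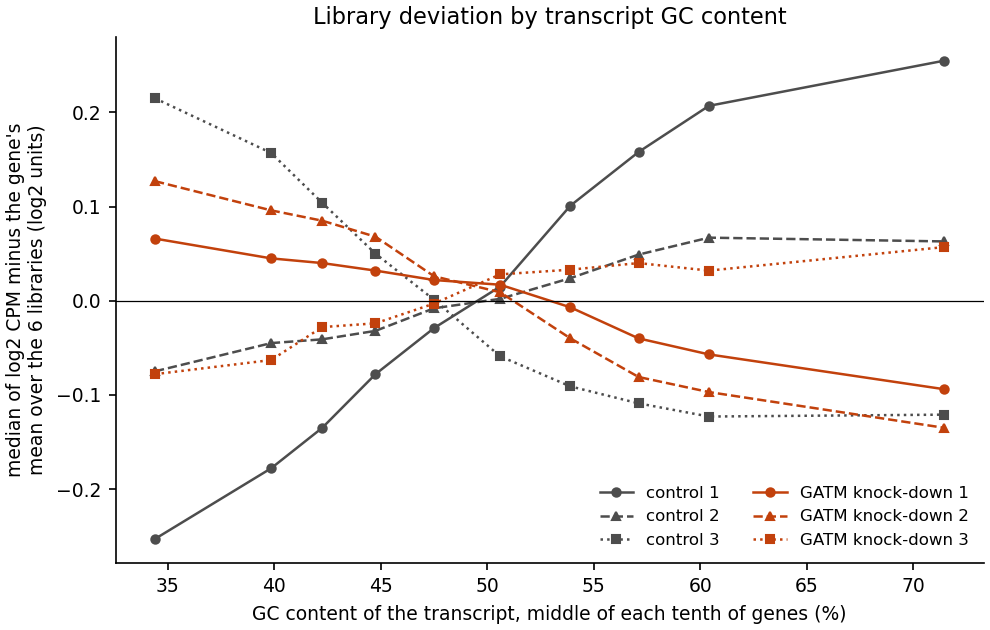
Median, over 10 equal classes of genes, of log2 CPM minus the gene's mean over the 6 libraries (vertical axis, log2 units), against the GC content of the transcripts in percent (horizontal axis), one line per library. Control 1 runs from -0.25 at the lowest GC content to 0.26 at the highest and control 3 from 0.21 to -0.12, so libraries of one group lie on opposite sides of 0.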

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

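GATM and the other 105 genes named by rule kept their direction under every alternative run for them; 16 lost their call when 1 library was left out and 12 under another alternative. The set tests of the 16 called lists kept their direction in each alternative fit, but the NF-kB median turned positive without control 3 (0.0234) and with GC content and length offsets (0.0049). They kept their call in 92 comparisons and lost it in 4 with 1 library left out, and kept it in 192 and lost it in 16 elsewhere; camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05). Leaving out 1 library at a time gave 2560 to 6032 changed genes, 1376 to 2970 higher and 1130 to 3062 lower. Offsets for GC content, added after the data were seen, gave 6440 changed and 3464 higher genes, and with length 6520 and 3523. A threshold of 0.01 left 2253. Tests on FPKM gave 1275 lower genes and 223 over 2-fold (pseudocount 1), 1268 and 487 (0.1), or 1096 and 221 (no filter); the pseudocount shrinks fold changes of weakly expressed genes, and FPKM scales by library totals, which on counts gave 1473 lower genes. With the replicate number as a block, 2814 genes changed, of which 2806 were shared, and 1266 were lower; the G2 and M list (adjusted p = 0.0607) and GAMT (0.0696) lost their call. Same-numbered libraries correlated at -0.10, -0.03 and -0.32, and no library correlated best with its own number. The deviations correlated here also carry each library's GC trend, so they cannot tell whether the numbers pair cultures. The set test of the uncalled filopodia list turned upward, with medians of 0.0508 (library totals), 0.0431 and 0.0433 (FPKM, pseudocount 1 and 0.1), 0.0508 (FPKM, no filter), 0.0074 (GC content) and 0.0035 (GC content and length). With 1 library left out its median ran from -0.0376 to 0.0030, and the test turned upward only without control 1. On FPKM the uncalled basal-like list (0.0163, 0.0250, 0.0124) turned downward in the test, as did the classical list without a filter (0.0227); with 1 library left out the basal-like median ran from -0.1816 to 0.0536, and the test turned only without control 3. The cause was not tested. In simulated counts, where far fewer genes changed than in the data, the test recovered 68.7% of genes changed 1.5-fold. With a GC trend per library added it recovered 41.8%, but the simulated dispersions already held the spread of that trend. These rates therefore do not carry over to the real comparison, and the share that depth alone limits was not tested.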

Other observations

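The genes in this paragraph were chosen after the values were seen; KRT8, KRT18, KRT19, KRT7, EPCAM, COL3A1, VIM, CDH2, FN1, HMGA2 and MYC are members of lists counted above. TXNIP and ARRDC4, which encode arrestin-like proteins that respond to glucose, rose with log2 fold changes of 3.42 and 2.14 (edgeR quasi-likelihood test). Of keratins of simple epithelia, KRT8 rose from 837 ± 84.6 to 2470 ± 105 CPM (1.56), KRT18 by 0.93 and KRT19 by 0.67, while KRT7 had a log2 fold change of -0.16 and did not pass. The adhesion gene EPCAM (2.05) and the intestinal transcription factor CDX2 (2.08) rose. Of genes linked to a mesenchymal state, COL3A1 fell by 1.12, while VIM, CDH2 and FN1 had log2 fold changes of -0.06, -0.01 and 0.12 and did not pass. HEY1, a Notch target, fell by 1.47, the hypoxia-responsive STC1 by 2.24 and the gap junction gene GJB2 by 1.86. MYC and HMGA2 had -0.09 and -0.02 and did not pass.

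Log2 fold changes of genes adjacent in gene order correlated at 0.139 over 13774 placed genes, above the highest of 2000 permuted orders (0.024; p = 5.00e-04, the smallest they can give). Permuted orders also lose the similar GC content of neighbours and the reads that overlapping or related neighbours share. The correlation therefore does not by itself show regulation by position. The run of 20 tested genes from ARMCX1 to MORF4L2, picked after it was seen, had a median of 0.57, with 16 higher and 0 lower. Of these, 13 have symbols of related gene families whose members can share reads (12 higher, median 0.59). WBP5, NGFRAP1 and BHLHB9 are older symbols of further members of these families. Of the rest, MORF4L2 rose (log2 fold change 0.44, edgeR adjusted p = 0.0066). ZMAT1, TMSB15A and LINC00630 did not pass (edgeR adjusted p = 0.0597, 0.1726 and 0.0617). Of 13337 windows of that size, 49 had a median as large. These windows overlap, so the 49 are not separate regions.

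Of the tests below, those on genomic DNA, sequencing depth, carry-over of RNA without a poly(A) tail and more cells in S phase were chosen only after the result was seen. Bootstrap intervals below are over genes, which are not independent, and leave out the spread between libraries. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 4276 changed genes (2216 higher, 2060 lower, 844 over 2-fold) and the highest other gave 0 with edgeR and 0 with DESeq2 (43 to 1952 at an unadjusted p under 0.05 in edgeR); for lists the real split gave 16 and the highest other 10. The epithelial, stress response and interferon lists each passed in 8 of the 9 other splits and the histone list in 7, in one direction or the other; a mixed split still holds part of the group difference. In 1 of 10 splits, the real one, each of these was as large. Every other split has libraries of both groups on each side, so the group difference adds to the spread within a side. Gene tests on such splits are bound to make few calls, so their 0 is no measure of chance.

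The ribosomal protein and oxidative phosphorylation lists had lower medians in knock-down cells and differed between control libraries; 52 of 77 and 54 of 72 members did not pass, nor did either list with an estimated correlation (adjusted p = 0.5258 for both) or in fry (0.0962 for both). With offsets for GC content and length the median was -0.154 (95% bootstrap interval over genes -0.201 to -0.113) for the ribosomal list and -0.140 (-0.197 to -0.081) for oxidative phosphorylation, against -0.21 for both without offsets. Without control 1 the medians were -0.160 (-0.192 to -0.119) and -0.150 (-0.205 to -0.089). The intervals treat genes as independent, though estimated correlations between members were 0.48 and 0.30, so they are too narrow. Both medians stayed negative with the offsets and without control 1. These values cannot tell whether the trend or control 1 accounts for the whole of the difference. Either may account for part of it. An effect of the knock-down remains an untested hypothesis, and RNA quality, for which the files hold no measure, stays open.

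Weakly expressed genes were higher in knock-down libraries. With genes classed by 1 control, their excess in CPM per kilobase over the other controls was at least 14.90 times larger (95% bootstrap interval 12.85 to 17.32) for genes of 1 to 3 CPM than for genes without a count, whereas genomic DNA would give the same excess in both. After thinning to one total, the lowest knock-down library still detected 531 genes more than the highest control library, and with offsets for GC content and length the median of genes under 3 CPM was 0.337 (0.305 to 0.373). Depth and the trend are thus each unlikely to account for it, as is genomic DNA for the genes of 1 to 3 CPM. Genes without a count in 1 control also had a small excess, 0.01311 to 0.01510 CPM per kilobase. The ratio therefore cannot decide whether a little genomic DNA added to the number of genes detected. RNA from other cells or from other libraries of the same sequencing run was not tested, so this and an effect of the knock-down stay open.

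Histone transcripts, most of which lack a poly(A) tail, had a higher median while the S phase list had a lower one; 26 of 45 S phase genes did not pass, and with an estimated correlation neither list did (adjusted p = 0.0503 and 0.3357). The median of 53 small nucleolar and Cajal body RNA genes was 0.031 (-0.179 to 0.221), against 1.09 for the histone list. These RNAs are mostly short and many lie within other genes, so they need not follow histone transcripts. Their median therefore cannot decide on a carry-over of RNA without a tail. With offsets for GC content and length the histone median was 1.165 (0.892 to 1.804). Without offsets the S phase median was -0.174 (-0.322 to -0.110), which is not what more cells in S phase would give. Carry-over of RNA without a tail and an effect of the knock-down stay open. Off-target effects of the knock-down were not tested for any pattern, since no construct sequence is given.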
